A study of Mus musculus with 2 samples.

How the data were processed

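RNA was sequenced from 2 cultures of the mouse embryonic stem cell line CCE, 1 infected with a control shRNA against luciferase and 1 infected with an shRNA against Zfp217. Per the labels' protocols, cells grew without feeders in serum and leukemia inhibitory factor (LIF). Puromycin, given there as 1 mg/mL, was added 4 days after infection and kept for 5 days before harvest. Total RNA was treated with DNase and depleted of ribosomal RNA, and libraries came from a strand-marking total RNA kit, per the labels' protocols. The submitters' processing notes name BWA 0.7.3 and the genome build mm9. The read counter, the annotation release and the strand setting of the counting are not given in the sources used here.

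The deposited table holds 1 line per RefSeq entry, 16649 in all (16219 protein-coding and 430 noncoding accessions), under 13229 gene symbols. It gives raw read counts and, per the file headers, normalized values on a log2 scale for each library. The deposited log2 values equal log2 of the count times 1 factor per library, 1 for the control and 1.48 for the Zfp217 shRNA library, with no pseudocount. No entry departed from this by more than a relative deviation of 1e-09, and the ratio of the column totals was also 1.48. The lowest counts were 12 in the control and 5 in the Zfp217 shRNA library, and the lowest sum of both was 86, so entries with few reads had been removed before deposit. Deposited counts summed to 48588363 in the control and 32735257 in the Zfp217 shRNA library. These sums count some reads more than once, because isoforms of a gene share reads: among 2260 symbols with more than 1 entry, the lowest entry held a median 94.5% of the count of the highest.

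The table holds 3 libraries, and the labels describe 2 samples. The columns named for luciferase were taken as the control shRNA sample. The columns named sh2 were taken as the Zfp217 shRNA sample because the deposited table is titled as the comparison of the luciferase hairpin with sh2. The labels do not name the hairpin, so this match rests on the title and on neither the order of the columns nor their values. The other library, with 2 columns of per-sample values, matched no label and was not used here.

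With 1 library per group, the spread between cultures could not be estimated, and no p-value was computed across genes. Each gene was represented by its entry with the highest mean, and differences are the deposited log2 values of the Zfp217 shRNA library minus those of the control. Intervals of 95% are exact Clopper-Pearson intervals on the Zfp217 shRNA share of a gene's summed counts, converted to a log2 difference with the authors' factor. They cover counting error only, since PCR copies without molecular identifiers are not independent molecules. Counts by size used a threshold of 2-fold among the 9922 genes with a mean normalized count of at least 333.1, the lower quartile of all genes, which is called the floor. A stricter floor was the median, 1009.5.

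Before the data were examined, 36 gene lists were fixed for pluripotency, lineages, RNA methylation, chromatin, signalling, metabolism, stress, housekeeping classes and other cell types. For each list with at least 5 genes above the floor, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. These percentiles describe 2 libraries and are not tests of the shRNA. Of the 36 lists, 30 had a percentile, 4 had too few genes and 2 (Hox genes and mitochondrially encoded genes) had none above the floor.

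The named genes were also fixed by rule: Zfp217, the 12 highest and 12 lowest differences above the stricter floor, up to 4 members of each list with the largest absolute difference above the floor, and every measured member of the m6A and core pluripotency lists. Further members of some lists were named after their values were seen, mainly those that went against their list or lay below the floor. Clone and predicted names, small RNAs, histones and mitochondrial genes were left out of the 12 highest and 12 lowest. A member of 1 list that the rule names is not reported here. Older symbols were matched to list members through RefSeq accessions in a reference gene table of a later mouse assembly, which was used for names only and matched 16262 entries. Coordinates are those of the deposited table on mm9, counted from 1. In that table, 12 named genes overlap another gene on the other strand and 2 overlap a gene on the same strand. Reads of such pairs may not be separable without the strand setting, and the partner is named where such a gene is discussed.

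Alternatives covered pseudocounts of 0.1 and 5, no floor and the stricter floor, centring on the median gene, centring within expression bins, summing or taking the median over entries, thresholds of 1.5-fold and 4-fold, raw counts scaled by TMM in edgeR, and random lists unmatched or matched on length. Centring within bins of transcript GC content, and scaling without small noncoding RNA genes, were chosen after seeing the data, as were TMM scaling and centring within expression bins for the level of Zfp217. GC content came from reference transcripts and was found for 98.0% of genes. The procedure was tested on simulated counts for the 9922 genes of this comparison. These counts held Poisson counting noise only, with no spread between cultures. The simulation therefore checks the calculation, and cannot show how often unchanged genes or lists pass the limits in real cultures. All planted log2 changes of 1.5 were recovered past 2-fold (100% in each direction, 100 genes each), 0 unchanged genes passed 2-fold, and 95.4% of intervals held the true value. Planted lists of 15 genes shifted by 0.5 reached percentiles 100 and 0, and an unchanged list lay at 40.1. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.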

Results

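Gene expression was measured by RNA sequencing in mouse embryonic stem cells of the line CCE after knockdown of Zfp217, a zinc finger transcription regulator, and in cells carrying a control hairpin against luciferase. The series title places the comparison within a study of Zfp217 in N6-methyladenosine (m6A) methylation of RNA. Each group had 1 library, with 48588363 deposited counts in the control and 32735257 in the Zfp217 shRNA library. No difference below therefore has a replicate check, and intervals in parentheses are 95% intervals for counting error only. The columns used for the Zfp217 shRNA library carry the name sh2, which was tied to that sample by the title of the deposited table and not by its label.

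Zfp217 transcripts were lower in the Zfp217 shRNA library. Zfp217 (NM_001159683; mm9 chromosome 2, 169934142 to 169968175, minus strand) had 5070 counts in the control and 2146 in the Zfp217 shRNA library, or 3186 after normalization. The log2 difference was -0.67 (-0.74 to -0.60), which is 1.59-fold lower (1.51 to 1.67). The target thus went in the direction of the label. However, 1831 of the 9922 genes above the floor were at least 1.5-fold lower. A difference of this size therefore does not settle whether sh2 is the labelled sample.

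The 12 genes with the highest log2 differences are named here by rank, and no shared function among them was tested. Enox1 (NM_172813; chromosome 14, 77556622 to 78121214) was 11.3-fold higher (10.2 to 12.6), with normalized counts of 417 in the control and 4731 in the Zfp217 shRNA library. Id3, an inhibitor of basic helix-loop-helix factors and a target of BMP signalling, was 10.6-fold higher, and its relative Id2 was 6.75-fold higher. Fgfbp1, which binds and releases FGFs, was 10.1-fold higher. Thbs1 and Cyr61 (now Ccn1), secreted matricellular proteins, were 6.93-fold and 6.22-fold higher, and Tagln, an actin-binding protein whose locus overlaps Pcsk7 on the other strand, was 6.45-fold higher. The carbonic anhydrase Car2 was 6.17-fold higher. The neurofilament gene Nefl was 5.41-fold higher and Nes, which encodes nestin of neural progenitors, was 5.16-fold higher. Bend3 and Jub (now Ajuba) completed the 12 highest, at 5.20-fold and 4.86-fold.

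The 12 genes with the lowest log2 differences were taken by rank in the same way. Rab3il1 (NM_144538; chromosome 19, 10092717 to 10110076) was 11.2-fold lower and the transglutaminase gene Tgm2 was 10.9-fold lower. Bmf, a BH3-only member of the BCL2 family, was 8.64-fold lower. Txnip, which encodes a thioredoxin-binding protein that restrains glucose uptake, was among the abundant transcripts of the control, with 84923 normalized counts against 10669 in the Zfp217 shRNA library, 7.96-fold lower. Hk1, a hexokinase of the first step of glycolysis, differed by -2.58 on the log2 scale. The phosphatase gene Inpp5d was 7.12-fold lower and the adhesion molecule gene Pecam1 was 6.63-fold lower. Kdelr3 (7.93-fold, overlapping Ddx17 on the other strand), Ttyh2 (6.97-fold), Capn5 (6.50-fold), Adc (now Azin2, 5.65-fold) and Padi2 (5.64-fold) completed the 12 lowest.

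**Figure D1:**
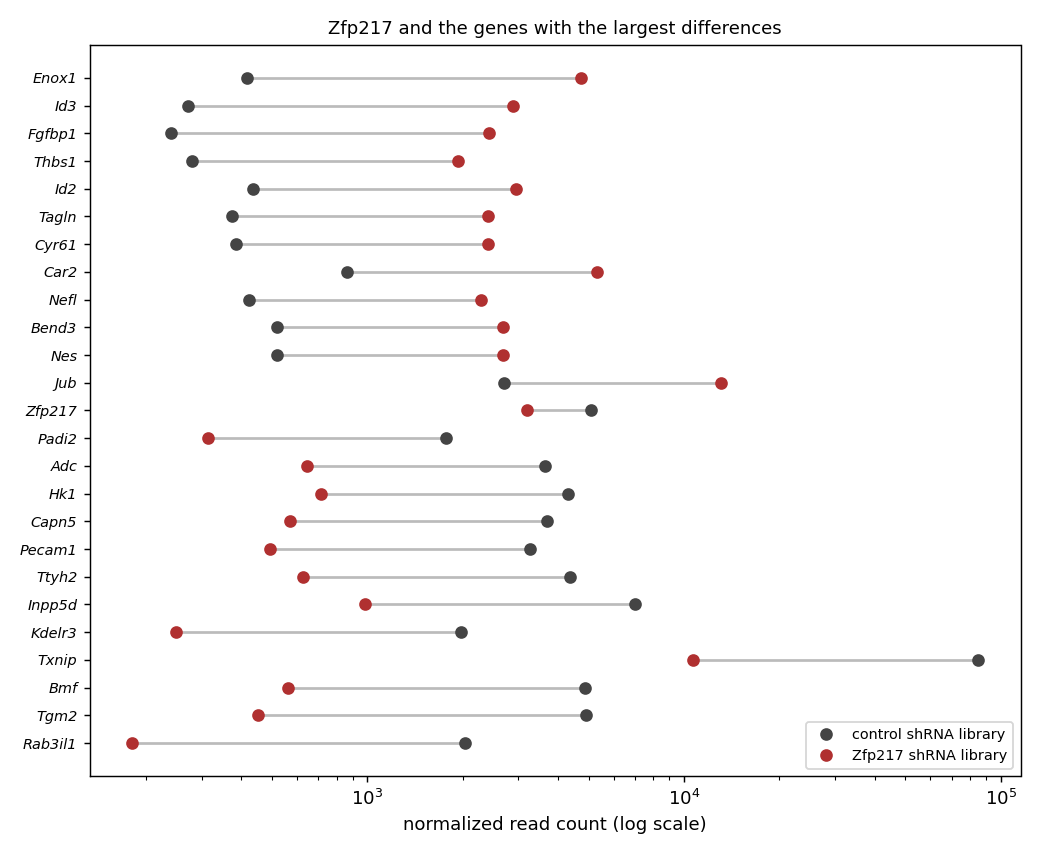
Normalized read counts (log axis) of Zfp217 and of the 12 genes with the highest and the 12 with the lowest log2 difference, each with 1 point for the control shRNA library and 1 for the Zfp217 shRNA library. Zfp217 lies at 5070 in the control and 3186 in the Zfp217 shRNA library, a smaller gap than that of any other gene shown.

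Among the 9922 genes above the floor, 295 were at least 2-fold higher and 712 at least 2-fold lower in the Zfp217 shRNA library, together 10.1% of the genes. The bound of the counting interval nearest to no difference was itself past 2-fold for 220 of the higher and 491 of the lower genes. The higher genes made up 29.3% of those past 2-fold with the authors' scaling, 40.8% with TMM scaling, 41.3% after centring within expression bins and 40.7% after centring within GC bins. The median of all genes was -0.07 with the authors' scaling and 0.03 with TMM.

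Genes of the formative and primed epiblast, the stages that follow naive pluripotency in the embryo, were higher in the Zfp217 shRNA library. Of 13 such genes above the floor, 9 were at least 2-fold higher, 0 at least 2-fold lower, and 12 lay above 0. The list's median log2 difference was 1.72, above all 10000 matched random lists (percentile 100). Sall2 was 7.60-fold higher, Zic2 was 4.98-fold higher, Pou3f1 (also called Oct6) was 4.29-fold higher and the epithelial regulator Grhl2 was 3.79-fold higher. Dnmt3b, Dnmt3l and Dnmt3a, genes of de novo DNA methylation, belong to this list and to that of DNA methylation. They were 3.02-fold, 2.48-fold and 1.30-fold higher.

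Core pluripotency genes did not move as a group. Of 28 above the floor, 5 were at least 2-fold higher and 4 at least 2-fold lower, and the median of 0.11 lay at percentile 84.3, while the mean was -0.02. Pou5f1 (Oct4) and Zfp42 (Rex1) differed little, at 0.05 (0.03 to 0.07) and 0.17 (0.14 to 0.19). Genes lower by at least 2-fold were Tbx3 (3.73-fold), Dppa5a (2.76-fold), Tcfcp2l1 (now Tfcp2l1, 2.17-fold) and Fgf4 (2.17-fold). Klf4 was 1.82-fold lower, Nanog, which overlaps Nanogpd on the same strand, was 1.56-fold lower, Esrrb was 1.53-fold lower and Sox2 was 1.35-fold lower. Genes higher by at least 2-fold were Gdf3 (2.70-fold), Mycn (2.46-fold), Dppa2 (2.44-fold), Lin28 (now Lin28a, 2.13-fold) and Nr0b1 (2.03-fold). Myc was 5.32-fold higher, at 79 and 420.1 normalized counts, below the floor.

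The remaining core genes lay within 2-fold. Prdm14 (-0.73), Tcl1 (-0.88), Tdgf1 (-0.71), Klf2 (-0.42) and Fbxo15 (-0.19, overlapping another transcript on the other strand) were below 0 on the log2 scale. Klf5 (0.29), Nr5a2 (0.38), Utf1 (0.39), Rif1 (0.40), Dppa3 (0.49), Dppa4 (0.61), Sall4 (0.79) and Trim28 (0.81) were above 0.

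**Figure D2:**
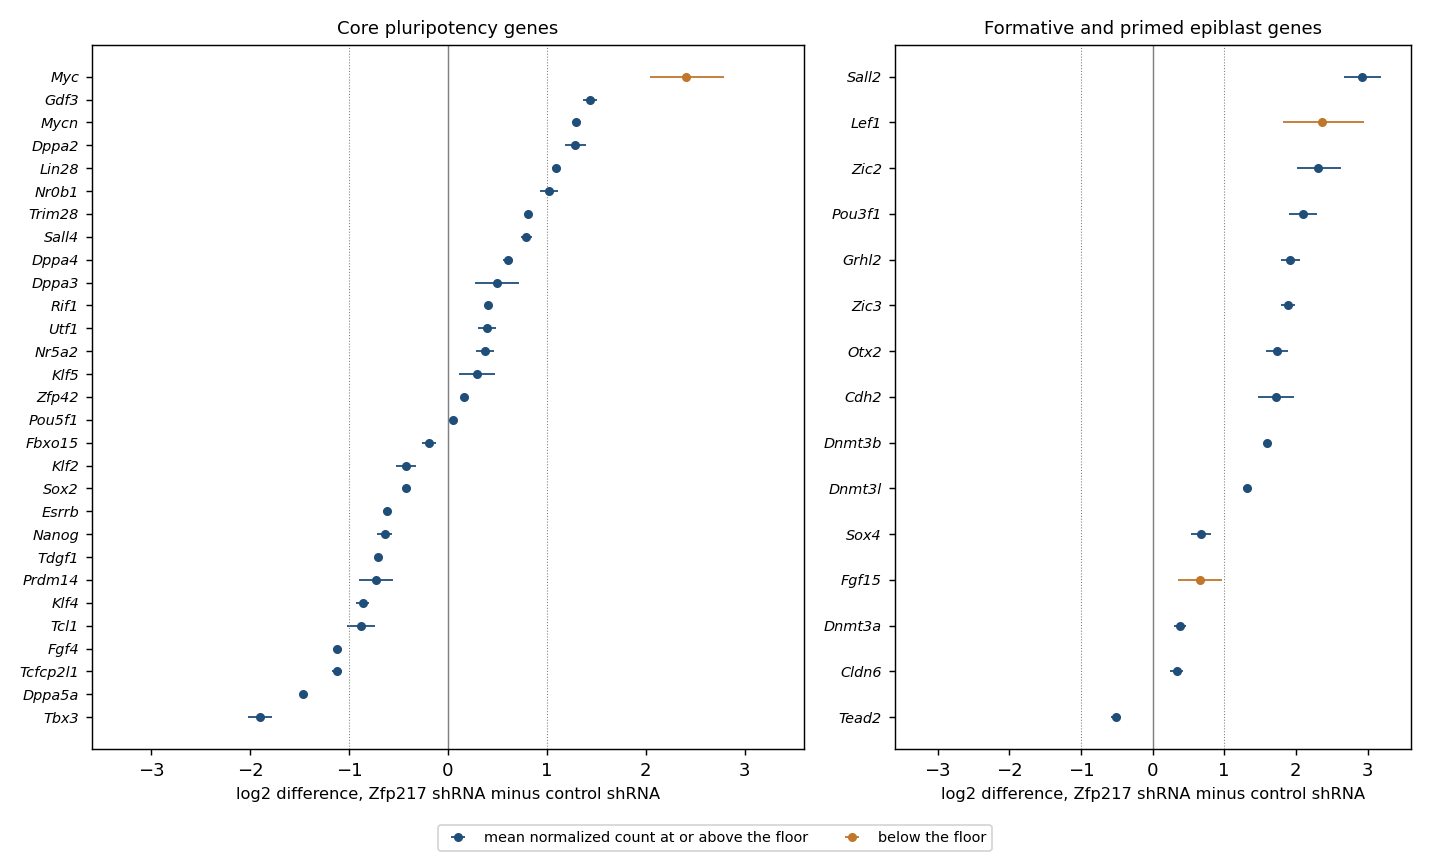
Log2 difference (Zfp217 shRNA minus control shRNA) of each measured core pluripotency gene and each measured formative or primed epiblast gene, with bars for the 95% counting interval. Dotted lines mark 2-fold. Core pluripotency genes spread from -1.90 (Tbx3) to 1.43 (Gdf3) above the floor, and all formative and primed genes above the floor except Tead2 (-0.51) lie above 0.

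Genes of the LIF and STAT3 pathway, which holds mouse embryonic stem cells in the naive state, were lower as a group. The median of 12 genes was -0.49 (percentile 0.24), with 8 below 0 and 2 at least 2-fold lower. The feedback inhibitor Socs3 was 2.08-fold lower, the kinase genes Pim1 and Jak1 were 1.94-fold and 1.84-fold lower (Jak1 overlaps Raver2 on the other strand), and Tcfcp2l1 was lower as above. Of the 12, 3 are also core pluripotency genes.

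Targets of FGF-ERK signalling, and a joint list of Nodal and BMP targets, were higher as groups. For FGF-ERK targets the median of 10 genes above the floor was 0.70 (percentile 99.99), with 9 above 0, and that of all 13 measured genes was 0.37 (percentile 99.5), since Egr1 (-0.54), Fos (-0.34) and Ier3 (0.17) lay below the floor. The feedback inhibitor genes Dusp6, Spry4, Spred1 and Spry2 were 2.98-fold, 2.87-fold, 1.88-fold and 1.87-fold higher. For Nodal and BMP targets the median of 10 genes was 2.15-fold higher (percentile 100), with 6 at least 2-fold higher, among them Id3, Id2, Id1 (log2 1.32) and the SMAD corepressor gene Skil (2.24-fold). Lefty2 was 2.10-fold higher, while Lefty1 (0.33) and Smad7 (-0.05) differed less. Tdgf1 and Nodal were 1.63-fold and 1.27-fold lower, and below the floor Smad6 was 3.95-fold lower, at 428 and 108.4 normalized counts. The list joins both pathways, and Nodal targets were not tested alone. Without the floor the median of 12 was 0.70 on the log2 scale (percentile 100). Only 4 Wnt targets lay above the floor, too few for a percentile. All 4 were higher: T by 10.2-fold, Notum by 3.20-fold, Ccnd1 by 2.77-fold and Znrf3 by 1.42-fold. T had 71 normalized counts in the control and 721.4 in the Zfp217 shRNA library. Of all 12 measured Wnt targets, 6 were lower, among them Axin2 (-0.12) and Tcf7 (-0.87), and the median without the floor was 0.23 (percentile 98.97). Also below the floor, Sp5 was 38.7-fold higher, at 12 and 464.6 normalized counts, and Lef1 was 5.17-fold higher, at 35 and 181.1.

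Lineage markers went in different directions. The median of 8 neuroectoderm genes was 0.58 (percentile 99.87), with 6 above 0 and 2 below. Nes, Gbx2 (4.18-fold) and Pax6 (2.04-fold) were higher, and Neurod1 and Ncam1 were 2.29-fold and 1.51-fold lower. Below the floor, Sox1 was 2.05-fold lower, at 161 and 78.7 normalized counts. Of mesoderm and primitive streak genes only T (brachyury) and Bmp4 (2.19-fold higher) lay above the floor, and the median of all 7 measured was 0.56 (percentile 99.6). Below the floor, Pdgfra and Mesp2 were 2.87-fold and 1.81-fold lower. Wnt3 and Kdr were 3.18-fold and 1.48-fold higher there, and Isl1 was at 0.10 (-0.29 to 0.49). The median of 7 endoderm genes was -0.90 (percentile 0), with Cubn 2.72-fold, Col4a2 2.65-fold, Col4a1 2.35-fold and Apoe 1.87-fold lower, and 5 of the 7 are also basement membrane genes. The trophectoderm list, with 5 genes above the floor, had a median of 0.88 (percentile 100) that came from the simple-epithelium keratins Krt18 (2.18-fold higher), Krt8 (2.10-fold) and Krt19 (1.84-fold), while the trophoblast regulator Tcfap2c (now Tfap2c) was 1.97-fold lower. Without the floor the median of that list was -0.42 and it did not stand apart (percentile 14.4). Markers of fibroblasts, another cell type a culture could hold, had a median of -0.27 (percentile 31.2) in 6 genes, with Tagln higher, Fbn1 1.41-fold higher, and Mmp2 and Col5a1 2.12-fold and 1.67-fold lower. That median was 0.03 after centring within GC bins.

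Genes of the m6A machinery, the writers, erasers and readers of the mark, were slightly higher as a group. Of 20 above the floor, 16 lay above 0 and 0 differed by 2-fold, with a median of 0.29 (percentile 98.95). Among the writers, Mettl3, the catalytic methyltransferase, was 1.28-fold higher (log2 0.35, 0.24 to 0.47; its locus overlaps Tox4 on the other strand). Its partner Mettl14 was 1.22-fold higher (0.29, 0.12 to 0.46), Mett10d (now Mettl16) 1.21-fold, Wtap 1.16-fold, 1110037F02Rik (now Virma) 1.29-fold higher, and Rbm15b was at 0.58 (0.49 to 0.67). The value of Wtap depended on the entry: log2 0.21 for the entry used and 0.62 for the median over its entries. Rbm15 was lower at -0.20 (-0.29 to -0.11). The interval of Zc3h13 (-0.02, -0.12 to 0.08) and that of Cbll1 (0.24, -0.19 to 0.67, below the floor) included 0. Of the demethylase genes, Fto was 1.30-fold lower (-0.38, -0.54 to -0.22) and Alkbh5 was at 0.09 (0.02 to 0.15).

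Among the readers, Igf2bp1 was 1.94-fold, Hnrnpa2b1 1.83-fold, Ythdf2 1.60-fold and Ythdf3 1.53-fold higher. Ythdf1 (0.32), Ythdc1 (0.32), Hnrnpc (0.26), Igf2bp3 (0.22) and Ythdc2 (0.08, -0.01 to 0.18) lay closer to 0, and Igf2bp2 was 1.46-fold lower. After centring within GC bins the list median was 0.25 and no longer stood apart (percentile 95.3). Genes of the LSD1, CoREST and CtBP corepressors had a median of 0.04 in 13 genes (percentile 71.1), and -0.02 without the floor. Ctbp2 and Ctbp1 were 1.83-fold and 1.51-fold higher, and Zmym3 was 1.92-fold lower. Polycomb genes had a median of 0.12 in 14 genes (percentile 78.8), with Bmi1 1.84-fold, Jarid2 1.78-fold and Eed 1.64-fold higher and Ezh1 2.12-fold lower. The 12 genes of DNA methylation and its removal had a median of 0.21 (percentile 90.8), with Tet2 1.65-fold lower and Mbd3 1.43-fold higher.

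Basement membrane and collagen-processing genes were lower as a group. The median of 15 genes was -0.58 (percentile 0), with 13 below 0 and 4 at least 2-fold lower. Nid1 was 2.45-fold lower and Serpinh1, a collagen chaperone, was 2.12-fold lower, beside Col4a1 and Col4a2. Genes of the integrated stress response also were lower, with a median of -0.49 in 14 genes (percentile 0.14). Ddit3 (CHOP), which overlaps Mars on the other strand, was 5.89-fold lower, Ddit4 was 3.03-fold lower, Chac1 was 2.69-fold lower and the asparagine synthetase gene Asns was 1.93-fold lower. Within GC bins that median was -0.25 (percentile 2.41). Cholesterol synthesis genes had a median of -0.39 in 19 genes (percentile 0.51), with 15 below 0 and 0 past 2-fold. The sterol regulators Insig1 and Srebf2 were 1.96-fold and 1.91-fold lower, Fdft1 (overlapping Ctsb on the other strand) was 1.88-fold lower and Cyp51 was 1.76-fold lower.

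Targets of p53 had a median of -0.28 in 18 genes, at percentile 2.49, on the edge of the limit. Pltp (overlapping Ctsa on the other strand) was 3.31-fold lower and Sesn1, Ccng2 and Trp53inp1 were 2.04-fold, 2.03-fold and 2.03-fold lower. The p53 list did not stand apart in 7 of the 13 alternative settings: the stricter floor (percentile 9.17), unmatched random lists (8.66), expression-bin centring (8.33), random lists matched on length (8.06), no floor (2.70), scaling without small noncoding RNAs (2.60) and the median over entries (2.51).

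**Figure D3:**
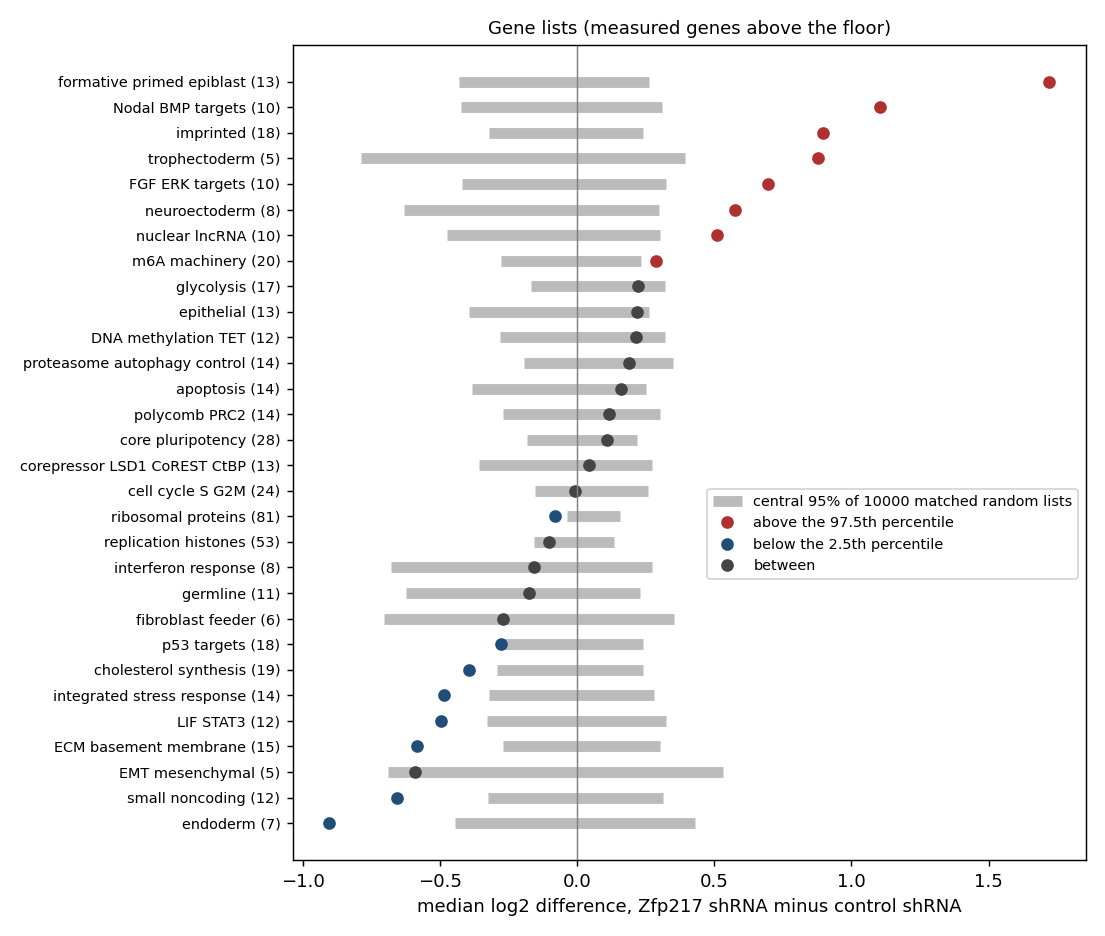
Median log2 difference (Zfp217 shRNA minus control shRNA) of each gene list with at least 5 genes above the floor, with the number of genes in parentheses. Grey bars span the central 95% of 10000 matched random lists. Of 30 lists, 8 lie above and 8 below their bars, from 1.72 for formative and primed epiblast genes to -0.90 for endoderm genes. The trophectoderm median turns to -0.42 without the floor, and the ribosomal protein median of -0.08 is 0.02 with TMM scaling, which moves all genes up alike and leaves this list below its random lists (percentile 0.155).

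If the genes within a list varied independently, as in the random lists, 1.5 of the 30 lists would be expected outside the limits. Lists whose genes vary together pass the limits more often, so this number does not measure chance here. In all, 16 of the 30 lists stood apart, 8 higher and 8 lower. Of these, 11 stood apart under all 13 alternative settings. They were formative and primed epiblast, neuroectoderm, FGF-ERK targets, Nodal and BMP targets, imprinted genes and endoderm. The others were LIF and STAT3, cholesterol synthesis, integrated stress response, small noncoding RNAs and basement membrane. Not all 13 settings test a percentile. Centring on the median gene, TMM scaling and scaling without small noncoding RNAs move a list and its random lists alike. The pseudocounts barely change genes above the floor. Such settings could hardly alter a call away from the limits, so stability rests on the remaining settings.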

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

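Centring within GC bins, scaling without small noncoding RNA genes and, for Zfp217, TMM scaling and centring within expression bins were chosen after seeing the data. The lower level of Zfp217 kept its direction in every setting tried for it, and left its counting interval only with TMM scaling, at -0.57. Genes at least 2-fold lower numbered 1239 without the floor, and with the stricter floor 174 were higher and 310 lower, since these settings keep more or fewer genes. At 1.5-fold 1020 were higher and 1831 lower, and at 4-fold 38 and 65, as the threshold itself sets. The other counts by size stayed within 1.5 times the reported ones, with more genes lower than higher throughout. The trophectoderm median reversed to -0.42 without the floor, when Krt7, Ascl2 and another gene of low counts entered. The ribosomal protein median (-0.08) was 0.017 with TMM scaling, which moves all genes up alike, and 0.023 within GC bins, and the list stayed below its random lists in both (percentiles 0.155 and 0.985). Of 384 list medians under alternatives, 373 kept their sign. Those under unmatched or length-matched random lists kept it by construction, since these settings leave the medians unchanged. Of the 11 sign changes, 3 were those of the trophectoderm and ribosomal lists, and 8 were in 5 lists that do not stand apart as reported. Lists lost their place outside the limits in 12 cases, 7 of them the p53 list, and gained one in 8, besides 2 lists too small for a percentile as reported. Of 93 named genes above the floor and past 2-fold, 79 stayed past it in every setting. The largest shifts were from 0.21 to 0.62 for Wtap and from 1.63 to 1.22 for B230206F22Rik (now Ftx), both with the median over entries. No paired analysis was possible because each group had 1 library, and without a second culture no setting measures biological spread.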

Other observations

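Imprinted genes were higher as a group in the Zfp217 shRNA library. The median of 18 genes was 0.90 (percentile 100), with 15 above 0, 7 at least 2-fold higher and 0 at least 2-fold lower. Peg10 was 3.36-fold higher, Mirg and Rtl1 of the Dlk1-Dio3 domain were 3.36-fold and 2.99-fold higher, and Mest, which overlaps Copg2 on the other strand, was 2.68-fold higher. Rian and Meg3, also of the Dlk1-Dio3 domain and with more counts than Mirg and Rtl1, were only 1.85-fold and 1.12-fold higher. Long noncoding RNA genes had a median of 0.51 in 10 genes (percentile 99.91), of which 2 are imprinted. The miR-17-92 host Mirhg1 (now Mir17hg) was 3.15-fold, B230206F22Rik (now Ftx) 3.09-fold, 2700023E23Rik (now Dancr) 2.09-fold and Snhg3 1.62-fold higher, but with the stricter floor the list did not stand apart (percentile 88.4). Small noncoding RNAs were lower, with a median of -0.66 and 12 of 12 below 0 (percentile 0.04). The minor spliceosomal RNA Rnu12 was 2.76-fold lower, Rnu1b2 was 2.38-fold lower, Snora43 (within Snhg7) was 1.89-fold lower and the RNase MRP RNA Rmrp was 1.69-fold lower.

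Death, cycle and metabolic genes moved within their lists in both directions. Among 14 apoptosis genes (median 0.16, percentile 92.1, and 97.6 within GC bins), the BH3-only gene Bcl2l11 (Bim) was 2.20-fold higher while Bmf, Casp9 (log2 -1.32) and Apaf1 (2.01-fold) were lower. Cell cycle genes had a median of -0.01 in 24 genes (percentile 28.3), which was 0.09 with TMM and 0.02 within GC bins. Ccne2 (overlapping Ints8 on the other strand) and Tyms were 1.79-fold and 1.59-fold higher, and Ccnb2 and E2f1 were 1.70-fold and 1.67-fold lower. Of CDK inhibitor genes, Cdkn1c was 2.45-fold higher, and Cdkn1b and Cdkn2a were 1.72-fold and 1.29-fold lower. The median of these 3 genes, which is the value of Cdkn2a, was -0.37, and -0.17 with the median over entries. Cdkn1a, below the floor, was 2.69-fold lower, at 419 and 155.9 normalized counts. Glycolysis genes had a median of 0.22 in 17 genes (percentile 90.2, and 97.7 among lists matched on length), with Slc2a1 1.87-fold and Ldha 1.72-fold higher and Hk1 and Pfkm (1.61-fold) lower. Germline genes (median -0.18, percentile 46.0, 11 genes) included Sycp3, Kit, Piwil2 and Dnd1, 3.01-fold, 2.82-fold, 2.67-fold and 1.78-fold lower. Sycp3 overlaps Chpt1 and Dnd1 overlaps Wdr55 on the other strand. Interferon response genes (median -0.16, percentile 51.8, 8 genes) were split, with the RNA sensor Ddx58 3.21-fold higher and Stat2, Xaf1 and Bst2 3.03-fold, 2.21-fold and 2.04-fold lower. Without the floor the 13 measured had a median of -0.70 and stood apart (percentile 1.14). Mesenchymal genes (median -0.59, percentile 4.31, 5 genes, and 2.48 within GC bins; 0.12 without the floor) held Tgfbi 3.58-fold and Fn1 1.80-fold lower and Cdh2 3.30-fold and Vim 2.20-fold higher. Epithelial genes had a median of 0.22 in 13 genes (percentile 95.1), with Grhl2, Krt18 and Krt8 higher and Cldn4 2.44-fold lower. That list stood apart as higher with the stricter floor (0.44, percentile 99.7), within expression bins (percentile 98.1) and within GC bins (98.1). Proteasome genes, a control class, had a median of 0.19 in 14 genes (percentile 82.1), with Psma5 1.41-fold and Psmb5 1.29-fold higher. Ribosomal protein genes had a median of -0.08 in 81 genes (percentile 0.345), and 0.02 with TMM scaling, which moves all genes alike. The list did not stand apart from unmatched random lists (percentile 45.1) or lists matched on length (16.9). Rpl22, Rpl28 and Rps28 were 1.35-fold, 1.33-fold and 1.32-fold lower and Rpl7l1 was 1.71-fold higher. Replication histone genes had a median of -0.10 in 53 genes (percentile 9.87), which was 0.11 within GC bins, with Hist1h4i, Hist1h1c and Hist1h2bg 2.20-fold, 1.96-fold and 1.86-fold lower and Hist1h2bh 2.01-fold higher. Of genes of the 2-cell-like state only Eif1a lay above the floor, 1.55-fold higher.

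The tests below with expression bins, other cell types, centring on the median gene and short transcripts were chosen after the values they measure had been seen, and the comparison with the control level of endoderm genes and that of the scaling test with TMM were added after the outcomes of these tests were known. The higher level of formative and primed epiblast genes was weighed against scaling, GC bias and mixed cells. If GC bias between the libraries were the cause, centring within GC bins would remove it, but the median of the list was 1.81 there. Centring within expression bins gave 1.88, which is no separate test of a scaling that depends on expression. The list already lay above the random lists matched on mean expression (percentile 100), so its outcome was set by that comparison. That comparison shows only that the list stood apart from genes of similar expression. Differentiated cells mixed into the culture cannot be told apart from a shift of all cells: neuroectoderm genes were higher, and the lower endoderm median (-0.90) decides nothing, since those genes had a median of 4847 normalized counts in the control, above the median gain of 993.9 of the formative genes. Also open and untested are a difference between 2 cultures unrelated to the hairpin and an off-target effect of the hairpin.

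The excess of lower over higher genes (712 against 295, a ratio of 2.41) was weighed against scaling, GC content and chromosome number. After centring on the median gene the ratio was 1.71, but with TMM it was 1.45 and within expression bins 1.42, between the values set for the presence and the absence of such a cause. Within GC bins the ratio was 1.46, also between these values, so neither scaling nor GC bias as the cause can be set aside, and each cannot be told apart from its absence. Gain or loss of a whole chromosome in most cells of a culture was set aside, since the chromosome farthest from the median of all genes, X, differed by 0.13. A change in a small share of the cells, or of part of a chromosome, could be missed by this comparison and stays open.

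The lower level of small noncoding RNAs, which took 3.98% of control counts and 2.41% of Zfp217 shRNA counts, could come from poorer recovery of short RNAs. Protein-coding entries under 600 bases, 182 in number, lay 0.032 above the median of all genes, which argues against a loss of all short transcripts. A loss limited to RNAs shorter than these entries, or strongly structured, stays open. No biological explanation was tested.

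After the highest and lowest genes had been seen, 5 further lists of genes not yet looked at were composed to test 5 hypotheses on the same 2 libraries, and members named here were picked after their values were seen. Txnip, Bmf, Sesn1, Ccng2 and Ddit4 are known FOXO targets, and 20 other FOXO targets or pathway genes had a median of -0.49, at percentile 0.08, with 17 below 0, and within GC bins -0.28 at percentile 1.86. Pik3ip1 (-2.12), Pink1 (-1.42) and Insr (-1.21) were lower, and Cited2 (1.19) and Irs2 (0.95) were higher. The 5 genes that prompted the hypothesis were picked because they were lower. Bcl2l11 (Bim), also a known FOXO target, was in neither the 5 nor the 20, and was 2.20-fold higher (log2 1.14, 1.02 to 1.26). Lower FOXO activity may be a candidate explanation for the lower genes only, and FOXO activity itself was not measured. Tagln, Acta2 and Tpm1 are actin cytoskeleton genes regulated by SRF, and 18 other such genes had a median of 0.67, at percentile 100, with 16 above 0. Ctgf (2.09), Actg1 (1.38) and Cnn2 (1.22) were higher, and Actg2 (-0.35) and Myh9 (-0.18) were lower. Higher SRF activity may account for them, and YAP signalling, which shares targets such as Ctgf and Cyr61, was not tested.

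Of the other 3 hypotheses, none passed its limit as reported. Hmox1, Mt1 and Mt2 were higher, but 18 other NRF2 targets lay at percentile 87.6. Abcg1, Cpt1a, Lpin1 and Pltp were lower, but 21 other LXR and PPAR targets lay at percentile 15.7. Mat2a was higher and Cbs lower, but 13 other genes of the methionine and S-adenosylmethionine cycle, which supplies the methyl donor of m6A, lay at percentile 96.0, inside the limits. That list was past the limit with the stricter floor (0.32, percentile 97.9) and within GC bins (0.40, percentile 98.9), so this negative result depends on those settings.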
